A study of Homo sapiens with 4 samples.

How the data were processed

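RNA sequencing of THP-1 cells treated for 48 h with 1 uM decitabine or DMSO was analysed from a single deposited gene table with 2 libraries per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, which does not mark strand. The submitters' processing notes name CASAVA 1.8, Trimmomatic, FastQC, HISAT2, StringTie, edgeR and the build GRCh38, with no version for the other tools. The series' design text names BWA and ANOVA, and TopHat and Cufflinks, instead, and which route gave the deposited table is not given in the sources used here. The table holds 60612 genes. Its per-library columns appear in 2 sets under the same names. Per the file headers and the values, the first set was taken as FPKM values computed by the authors, since its columns hold decimals. The second set was taken as raw counts deposited by the authors, since its columns hold whole numbers with different totals. How reads were assigned to overlapping gene models, and whether the counts were derived from estimated coverage, is not given in the sources used here. Without strand, reads of a gene and of an antisense partner cannot be told apart, and reads of overlapping genes or close paralogs can be assigned to either.

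Columns were matched to samples through the sample descriptions. Gene IDs were compared with GENCODE release 29 on GRCh38, where 58394 were found, 44945 of them with the same coordinates, so coordinates are those of the deposited table. GC content and length are those of the longest GENCODE transcript of each gene, and 18514 of the genes tested have them (98.5%). Exon overlap was taken from the same annotation.

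Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling (factors 1.02 and 1.00 for DMSO, 0.958 and 1.02 for decitabine), glmQLFit and glmQLFTest, two-sided, decitabine against DMSO without covariates, with Benjamini-Hochberg adjustment over the 18789 genes tested and a threshold of 0.05. The filter kept at least 99.96% of the counts of each library. The common biological coefficient of variation was 0.22. SE is the log2 fold change divided by the square root of the F statistic. CPM are counts per 1e+06 counts of the TMM-scaled library, given as mean ± SD over 2 libraries. For a gene without counts in a group, the fold is a lower bound against 3 counts over that group (0.0195 CPM for DMSO, 0.0191 CPM for decitabine). It uses the other group's counts pooled over its libraries, unless 1 library is named, so it can differ from the ratio of the printed mean. The FPKM values deposited by the authors entered only an alternative, limma 3.58.1 on log2(FPKM + 1) for genes with at least 1 FPKM in 2 libraries.

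Before the data were examined, 33 gene lists were fixed, and the 30 with at least 5 tested members entered camera with a preset correlation of 0.01, adjusted over the lists. None of the 14 calls held with an estimated correlation. That setting also takes its p-values from the few residual degrees of freedom of these libraries, which alone can lose a call. For the interferon list the unadjusted camera p went from 7.96e-16 to 0.0104, at an estimated correlation of -0.00377. That is below the preset 0.01, so for that list the lost call does not show that correlation between genes undid it. Other called lists had estimates above 0.01, up to 0.848 for the ribosomal proteins. There the unadjusted camera p went from 1.04e-09 to 0.387, and correlation can have added to the loss. Directional fry, which asks whether the genes of a list move on balance one way, gave 6 of the 14. Members are also counted after adjustment over the list alone. The genes named were fixed by a rule. It took the 10 largest rises and falls among called genes with a symbol, at least 1 CPM in a group and groups that do not overlap, then the 4 members of smallest p of each called list and 2 of each other list, and 7 genes always named (DNMT1, DNMT3A, DNMT3B, DCK, CDA, CDKN1A and GAPDH). EPCAM, COL3A1, LY75, NPTX1 and AC000093.1 were added after their values were seen.

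The test was checked on counts simulated from the means and library sizes of these libraries, with 200 genes changed. For decitabine against DMSO, with 18184 genes tested, 43.6% of 94 genes changed 2-fold and 79.8% of 94 changed 4-fold were recovered, none in the wrong direction, with 6 false calls among 122. A list shifted 1.5-fold was called and no other list was. Genes were simulated independently, at the trended dispersion and without GC or length trends. The list check therefore does not cover lists of correlated genes, such as the ribosomal proteins, with an estimated correlation of 0.848.

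Alternatives fixed beforehand were no filter, a stricter filter (50 counts in 2 libraries), RLE and upper quartile scaling, a robust variance prior, DESeq2 1.42.0, the replicate number as a block, each library left out, and thresholds with a 2-fold limit. Offsets for GC content and length (loess trends per library), limma on FPKM, leaving out genes that share exons on the same strand, and an estimated correlation with the offsets, without decitabine replicate 1, with the stricter filter or without overlapping gene models were added after seeing the data. Pseudocounts apply only to normalized values and were not varied for counts. Figures were drawn with matplotlib 3.10.9.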

Results

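THP-1 is an established human monocytic cell line derived from acute myeloid leukaemia. Cultures were exposed for 48 h to 1 uM decitabine or to the solvent DMSO, and RNA libraries made with a TruSeq kit were sequenced. Decitabine is a cytidine analogue that is incorporated into DNA, traps DNA methyltransferases and lowers cytosine methylation as cells divide. Each group held 2 libraries. The DMSO libraries summed to 67568868 and 84248580 counts and the decitabine libraries to 84027660 and 75263557, and between 22516 and 23554 genes had counts in a library. Libraries of the same group differed by more than sampling noise, with a chi-square per gene of 37.3 for DMSO and 70.3 for decitabine. The first principal component of log2 CPM (counts scaled to library size, per 1e+06) held 52.6% of the variance and separated the groups. The sample descriptions number the libraries of each group 1 and 3 while the titles call them replicates 1 and 2, and whether the groups had further libraries is not known. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Bounds taken from a count of 0 cover counting error only.

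The series title names the question as which genes decitabine induces. After 48 h, 236 genes rose and 29 fell, with 13 interferon response genes and 9 monocyte and macrophage genes among the rises. Of 18789 genes tested, 265 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 89.1% of these rose. Among the genes that rose, 214 were protein coding, 57 had a mean under 0.1 CPM in DMSO and 42 had no count in either DMSO library. In all 265 the 2 libraries of one group lay beyond both of the other, as did 54.4% of all genes tested, where chance gives 33.3%. The excess of rises turned without decitabine replicate 2, where 3934 genes were called and 44.4% of them rose (1748 up, 2186 down). Without decitabine replicate 1 the test called 449 genes (346 up, 103 down), without DMSO replicate 2 it called 732 (589 up, 143 down) and without DMSO replicate 1 it called 389 (329 up, 60 down). DESeq2 called 901 genes, of which 69% rose, and at an unadjusted p under 0.05 there were 3480 genes, of which 56.7% rose. Counts of list members given below for fits without a library, above all decitabine replicate 2, were not compared with the share of all genes called.

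**Figure D1:**
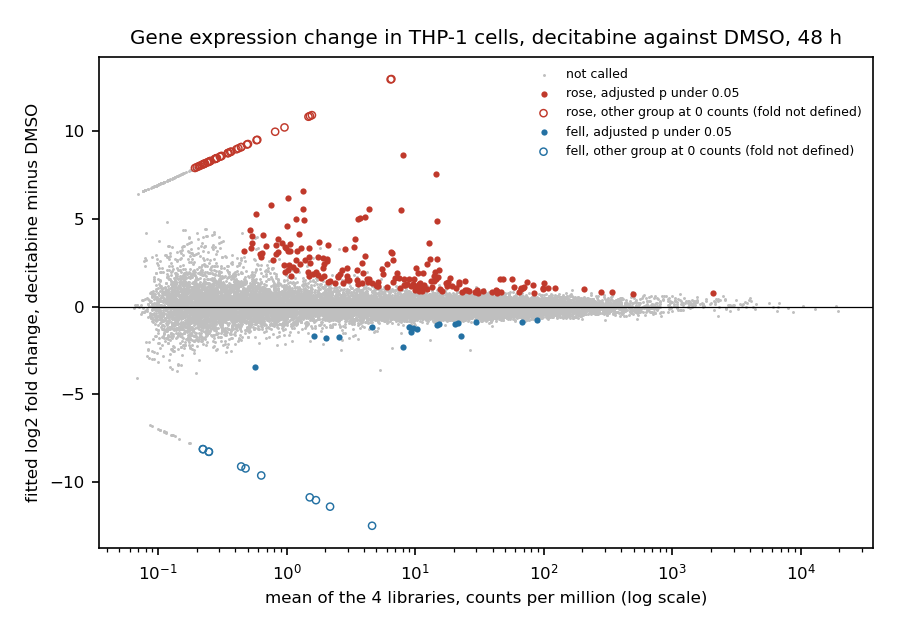
Fitted log2 fold change (decitabine minus DMSO) of the 18789 genes tested against the mean CPM of the 4 libraries on a log axis. Red points are the 236 genes that rose and blue points the 29 that fell, and open circles mark genes with no count in either library of the other group, whose fitted fold depends on the prior count and is not a measured fold.

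By fitted fold change, which depends on the prior count here, the 10 largest rises were all in genes without a count in DMSO. NPTX1 and MAGEA4, which had DMSO counts, rose by fitted folds of 399 and 190, above the lower bounds of 8 of the 10. SPARC, which encodes a collagen-binding matrix glycoprotein (ENSG00000113140, GRCh38 chromosome 5, 151661096 to 151686975), reached 13.1 ± 0.811 CPM (SD, n = 2) with decitabine. Against a floor of 3 counts over both DMSO libraries (0.0195 CPM) it was at least 669-fold higher. PRF1, the pore-forming protein of cytotoxic lymphocytes (ENSG00000180644, chromosome 10, 70597348 to 70602759), reached 12.9 ± 2.01 CPM and was at least 661-fold higher. The long non-coding RNA LINC02212 was at least 161-fold higher, the T cell costimulatory receptor gene TNFRSF4 at least 156-fold, the scaffold gene FRMD4A at least 152-fold and the zinc finger gene ZNF595 at least 98.6-fold. The remaining 4 were the fibrillar collagen gene COL11A1, the platelet glycoprotein gene GP1BB, the keratin gene KRT80 and the antisense RNA VAC14-AS1, with bounds between 51.1-fold and 83.3-fold. Adjusted p over the 10 ran up to 0.00221. LINC02212 and GP1BB share exons with another gene on their own strand, and SPARC, FRMD4A and VAC14-AS1 overlap exons of a gene on the opposite strand. The library kit does not mark strand, so the reads of these 5 genes cannot be assigned with certainty. GP1BB lies within the same-strand model AC000093.1, which had 3.80 CPM in DMSO and 25.55 CPM with decitabine (fitted fold 6.73). Reads of GP1BB can be assigned to that model, so its DMSO count of 0 and its bound are uncertain.

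Cancer-testis and germline genes, normally limited to germ cells and often silenced by promoter methylation, were higher as a list (camera adjusted p = 3.67e-09, and adjusted p = 0.252 with an estimated correlation). Of 54 members 13 had enough counts to test, and 11 of these were higher with decitabine. The filter admits a gene without counts in 1 group only through the other group. For such members, HORMAD1 and TEX11 among them, the direction was therefore fixed, and their values also enter the list call. The list median log2 fold change was 0.37 against a mean of 2.57. A single member, the melanoma antigen gene MAGEA4 (ENSG00000147381, chromosome X, 151912509 to 151925170), passed over all genes tested, and 6 rose when adjusted over the list alone. Over all genes 3 rose with RLE, upper quartile scaling or the robust prior, and 4 with DESeq2. The count stayed at 1 with no filter, the stricter filter or GC and length offsets. Without decitabine replicate 2 there were 4 that passed over all genes, with 3 without DMSO replicate 1 and 3 without DMSO replicate 2. MAGEA4 went from 0.155 ± 0.0679 to 29 ± 1.56 CPM (log2 fold change 7.57, SE 0.306, adjusted p = 1e-06). HORMAD1 and TEX11, genes of meiotic recombination, had no DMSO count and were at least 19.5-fold and 9.77-fold higher (12-fold and 7.63-fold from the lower decitabine library alone), with adjusted p of 0.0598 and 0.139. MAEL, of the piRNA pathway, had 0.105 CPM in DMSO and 1.06 CPM with decitabine (adjusted p = 0.0621).

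Type I interferon response genes gave the smallest p of the lists. Of 47 members tested 13 rose and none fell, 26 rose when adjusted over the list alone, and the median log2 fold change was 0.62 (camera adjusted p = 2.39e-14, and adjusted p = 0.252 with an estimated correlation). The count of 13 became 24 up and 2 down without decitabine replicate 2, 20 up without decitabine replicate 1, 22 up with DESeq2 and 4 up with no filter on low counts. LGALS3BP, a secreted galectin-binding glycoprotein, rose from 23.9 ± 1.75 to 72.7 ± 13.2 CPM (log2 fold change 1.61, SE 0.182, adjusted p = 0.00119). IFI27 rose from 39.9 to 108 CPM, IFITM1, which restricts viral entry, from 68.6 to 146 CPM, and the ubiquitin-like modifier ISG15 from 12.7 to 31.0 CPM, with adjusted p of 0.00133, 0.00751 and 0.0118. MHC class I and antigen processing genes were higher as a list (adjusted p = 0.0154, and adjusted p = 0.446 with an estimated correlation). There the immunoproteasome subunit gene PSMB9 rose by 0.78 on the log2 scale (adjusted p = 0.0458), and the other 16 members tested did not pass, over all genes or over the list alone, while 8 rose and 1 fell without decitabine replicate 2. That list was not called when gene models sharing exons on the same strand were left out (adjusted p = 0.359). MHC class II genes were higher in 11 of 11 members, with a median log2 fold change of 0.39 and no member past the threshold (list adjusted p = 0.0364, and adjusted p = 0.4 with an estimated correlation). The class II median was 0.25 without DMSO replicate 1. The class II call was lost without decitabine replicate 2 (adjusted p = 0.0857), without DMSO replicate 2 (adjusted p = 0.143), with the stricter filter (adjusted p = 0.0593) and without overlapping gene models (adjusted p = 0.0587).

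Monocyte and macrophage genes were higher as a list, with 9 of 46 members up and none down, 16 up when adjusted over the list alone, and a median log2 fold change of 0.63 (camera adjusted p = 3.1e-11, and adjusted p = 0.252 with an estimated correlation). The count of 9 became 15 up and 1 down without decitabine replicate 2 and 4 up with no filter. GPNMB, a glycoprotein of lysosomes in macrophages, rose from 28.4 ± 1.21 to 84.9 ± 4.84 CPM (log2 fold change 1.58, SE 0.161, adjusted p = 0.000486). The calcium-binding protein gene S100A9 rose from 57.0 to 143 CPM, the integrin alpha M gene ITGAM from 13.1 to 36.0 CPM and the inhibitory receptor gene CD300A from 7.44 to 20.6 CPM. Of 13 neutrophil granule genes tested, MMP9, encoding a gelatinase, rose from 3.46 to 22.7 CPM (adjusted p = 0.000232), and 4 rose when adjusted over the list alone. CAMP, CTSG and BPI were higher without passing (adjusted p = 0.0851, 0.101 and 0.106). The granulocyte list was called higher (adjusted p = 2.06e-05, and adjusted p = 0.4 with an estimated correlation), and 8 members rose without decitabine replicate 2. Its median log2 fold change of 0.41 was 0.24 without decitabine replicate 1, 0.61 without decitabine replicate 2 and 0.04 with offsets for GC content and length.

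NF-kB and inflammatory cytokine genes were called higher (adjusted p = 0.000178, and adjusted p = 0.252 with an estimated correlation), with 3 of 31 members up and 7 up when adjusted over the list alone. Without decitabine replicate 2 there were 7 up and 2 down, and 5 up without decitabine replicate 1 or DMSO replicate 2. IL32 rose from 4.74 to 18.2 CPM, TNF from 3.57 to 11.3 CPM and IL1B from 0.615 to 3.28 CPM, with adjusted p of 0.00119, 0.00287 and 0.00313. CCL3 went from 0.387 to 1.76 CPM and missed the threshold (adjusted p = 0.0538). In the inflammasome list IL1B was the 1 member of 16 that passed, and 5 rose when adjusted over the list alone. The count of 1 became 4 up and 1 down without decitabine replicate 2, 3 up without DMSO replicate 2 and 2 up without decitabine replicate 1. That list had a median log2 fold change of 0.08 against a mean of 0.42 (adjusted p = 0.0366, and adjusted p = 0.4 with an estimated correlation). The median was 0.19 without decitabine replicate 1, 0.15 without DMSO replicate 1, 0.13 without decitabine replicate 2 and 0.19 with offsets for GC content and length. The call was lost without decitabine replicate 2 (adjusted p = 0.113), without DMSO replicate 2 (adjusted p = 0.112) and with the stricter filter (adjusted p = 0.0662).

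Genes known as promoter-methylated tumour suppressors in leukaemia were higher as a list (adjusted p = 0.000155, and adjusted p = 0.252 with an estimated correlation), with 2 of 17 members up, 5 up when adjusted over the list alone, 7 up without decitabine replicate 2 and 4 up without decitabine replicate 1. CDKN1C, a cyclin-dependent kinase inhibitor (ENSG00000129757, chromosome 11, 2883213 to 2885775), rose from 3.57 ± 0.796 to 16.8 ± 0.45 CPM (log2 fold change 2.23, SE 0.226, adjusted p = 0.000485). IGFBP3, which binds insulin-like growth factors, rose from 0.594 to 2.35 CPM (adjusted p = 0.0174). CDKN1C is also imprinted, and with the imprinted non-coding RNA H19 it made up the 2 of 15 imprinted genes that rose, over all genes and over the list alone. The imprinted list had 3 up and 2 down without decitabine replicate 2. H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470) went from 0.0237 ± 0.0335 to 1.5 ± 0.417 CPM (adjusted p = 0.00333). It shares exons with another gene on its strand. As a list the imprinted genes did not pass (adjusted p = 0.156).

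**Figure D2:**
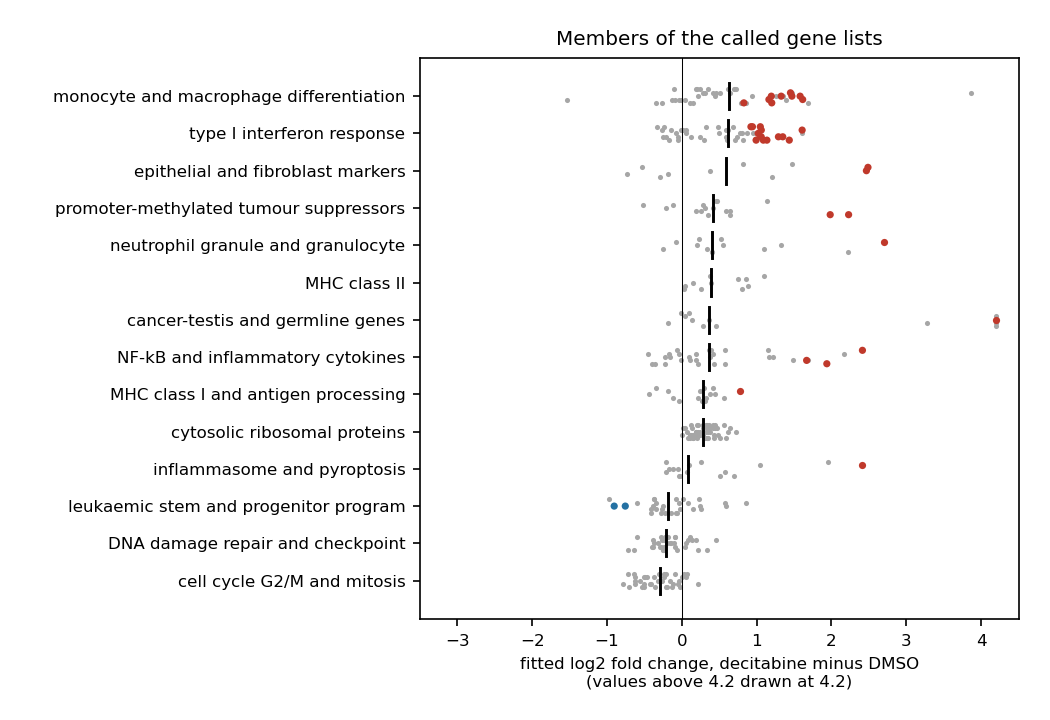
Fitted log2 fold change (decitabine minus DMSO) of every tested member of the 14 called gene lists, 1 point per gene, with the list median as a black bar. Red and blue points are members that rose or fell at an adjusted p under 0.05, grey points did not pass, and the interferon and monocyte lists hold 13 and 9 red points.

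The lists of other cell types had few members past the threshold. Of 10 epithelial and fibroblast markers tested, KRT8 rose from 1.85 to 10.2 CPM and the collagen chain gene COL1A1 from 1.16 to 6.53 CPM (adjusted p = 0.000356 and 0.00177), and 4 rose when adjusted over the list alone (list adjusted p = 0.000149, and adjusted p = 0.252 with an estimated correlation). Without decitabine replicate 1, without decitabine replicate 2 and without DMSO replicate 2, 4 passed over all genes in each case. COL6A1 and PDGFRB were higher without passing (adjusted p = 0.0672 and 0.0947), while EPCAM and COL3A1 had no count in any library. Of 22 T and NK cell markers only 4 could be tested, and PRF1 rose. NKG7 went from 16.8 to 26.2 CPM (adjusted p = 0.159), and 2 of the 4 rose when adjusted over the list alone. The mean fitted log2 fold change of the 4 was 3.69 against a median of 0.73, with 12.97 for PRF1. The list was not tested without PRF1. In the 5 settings where at least 5 T and NK markers could be tested (no filter and each library left out) that list was called by camera with the preset correlation. With an estimated correlation it was not called without decitabine replicate 1, and the other settings were not run that way. Of 9 B cell markers tested none passed over all genes and 2 rose when adjusted over the list alone (list adjusted p = 0.414), CD79B having the smallest p (adjusted p = 0.0672). Of 9 megakaryocyte genes GP1BA rose, at least 21.5-fold from no count in DMSO (list adjusted p = 0.228, and 0.0362 without overlapping gene models, where the adjusted p = 0.392 with an estimated correlation). Of 4 erythroid genes the ankyrin gene ANK1 rose from 1.66 to 6.21 CPM (adjusted p = 0.00432), and 2 rose when adjusted over the list alone. Of 3 neuronal genes tested none passed over all genes, and 1, the enolase gene ENO2, rose when adjusted over the list alone. Leaving out decitabine replicate 2 gave 2 T and NK, 1 B cell and 2 megakaryocyte genes up, leaving out DMSO replicate 2 gave 1 B cell gene, and 2 erythroid genes rose without decitabine replicate 1 and without DMSO replicate 1.

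Falls were fewer. The leukaemic stem and progenitor list was called lower (adjusted p = 0.0138, and adjusted p = 0.529 with an estimated correlation), with RUNX2 and CD38 down among 30 members, over all genes and over the list alone. RUNX2, a Runt-family transcription factor (ENSG00000124813, chromosome 6, 45328157 to 45664349), went from 111 ± 4.61 to 65.5 ± 5.87 CPM (log2 fold change -0.76, SE 0.155, adjusted p = 0.0408). CD38, a surface enzyme that consumes NAD, went from 27.9 ± 2.69 to 14.9 ± 2.49 CPM (log2 fold change -0.90, SE 0.191, adjusted p = 0.047). Without decitabine replicate 2 the list had 9 members down and 1 up. Both calls were lost without DMSO replicate 1 and with no filter on low counts, and that of CD38 also with limma on FPKM. Genes of G2/M and mitosis were lower in 35 of 40 members, with a median log2 fold change of -0.30 and no single gene past the threshold, over all genes or over the list alone (list adjusted p = 2.01e-07, and adjusted p = 0.377 with an estimated correlation). Without decitabine replicate 2, 16 of these fell, and with offsets for GC content and length 3 fell. TOP2A, the topoisomerase of dividing cells, went from 204 to 132 CPM, and the kinesin gene KIF20A from 28.0 to 17.9 CPM, with adjusted p of 0.102 and 0.103. With the offsets KIF20A passed (adjusted p = 0.0485), while the log2 fold change of TOP2A went from -0.63 to -0.26. DNA damage repair genes were called lower with no single gene past the threshold (36 tested, median log2 fold change -0.21, adjusted p = 0.0191, and adjusted p = 0.645 with an estimated correlation). That median was -0.06 without decitabine replicate 1, -0.38 without decitabine replicate 2 and -0.12 without DMSO replicate 1. Without decitabine replicate 2, 8 of these fell and 1 rose. The list call was lost without decitabine replicate 1 (adjusted p = 0.125), without DMSO replicate 1 (adjusted p = 0.0611) and with offsets for GC content and length (adjusted p = 0.525).

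Of the 10 largest falls by fitted fold change among called genes with at least 1 CPM in a group, 8 were in read-through or clone-named gene models. LSMEM1 and USP32P2 were not. Larger fitted falls than that of LSMEM1 were also called in genes under that limit. LY75-CD302, a read-through model (ENSG00000248672, chromosome 2, 159771851 to 159904710), had 9.25 ± 3.41 CPM in DMSO and no count with decitabine. From counts pooled over the group it was at least 497-fold lower, and from the lower DMSO library alone at least 358-fold. ISY1-RAB43, AL445685.3, AC087721.2 and AC004593.2 had no decitabine count either, and from the lower DMSO library alone were at least 154-fold, 32.3-fold, 77.6-fold and 29.2-fold lower. The DMSO libraries differed for these genes, AL445685.3 having 6.15 and 0.616 CPM (3.38 ± 3.91 CPM), AC087721.2 4.57 and 1.48 CPM, and AC004593.2 1.98 and 0.557 CPM. The call of AL445685.3 was lost with the robust prior (adjusted p = 0.462). LSMEM1, USP32P2, AC078927.1, AP001931.2 and BCL2L2-PABPN1 had log2 fold changes between -3.43 and -1.67. Of the 10, 9 share exons with another gene on the same strand, and AP001931.2 is not in the reference annotation, so its overlap is not known. Over all 28 falling genes found in the reference annotation the share with such overlap was 57.1%, against 16.9% of genes tested (Fisher's exact test, two-sided, p = 1.64e-06). For 15 of these, 1 overlapping partner each was examined, and other partners were not. None of the 15 partners was called, such as LY75 with 71.7 CPM in DMSO and 57.6 CPM with decitabine.

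None of the DNA methyltransferase genes passed at the RNA level. These data hold no measure of the proteins or of DNA methylation, so they do not show whether decitabine acted on them. DNMT1, DNMT3A and DNMT3B had log2 fold changes of -0.07, -0.09 and -0.06 (SE 0.146, 0.172 and 0.188), with adjusted p from 0.806 to 0.888, and none of 19 genes of the methylation machinery passed, over all genes or over the list alone (list adjusted p = 0.408), while 2 rose and 3 fell without decitabine replicate 2. The activating kinase gene DCK went from 46.9 to 35.1 CPM and the deaminase gene CDA from 2.97 to 4.08 CPM, without passing (adjusted p = 0.288 and 0.48). In the uptake and metabolism list of 17 tested genes the nucleoside transporter gene SLC28A3 rose from 0.203 to 1.86 CPM (adjusted p = 0.0114), and 1 gene rose and 1 fell when adjusted over the list alone. Over all genes 3 rose and 4 fell without decitabine replicate 2, and 2 rose without DMSO replicate 1. Its median was -0.12 (-0.009 without DMSO replicate 1 and -0.24 without DMSO replicate 2) and its mean 0.27, with camera lower (adjusted p = 0.546). CDKN1A, the p21 gene, was at 47.3 and 64.6 CPM (adjusted p = 0.188), and none of 31 p53 targets passed, over all genes or over the list alone (list adjusted p = 0.875, median -0.01, mean 0.003), while 4 rose and 3 fell without decitabine replicate 2. That median was 0.07 without decitabine replicate 1 and -0.07 without decitabine replicate 2. The latter fit called genes throughout, so counts from it do not by themselves mark a response of these lists. GAPDH was at 3414 and 3622 CPM (adjusted p = 0.778), with a log2 fold change of 0.09 that was -0.23 with the GC and length offsets and -0.12 without decitabine replicate 1.

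**Figure D3:**
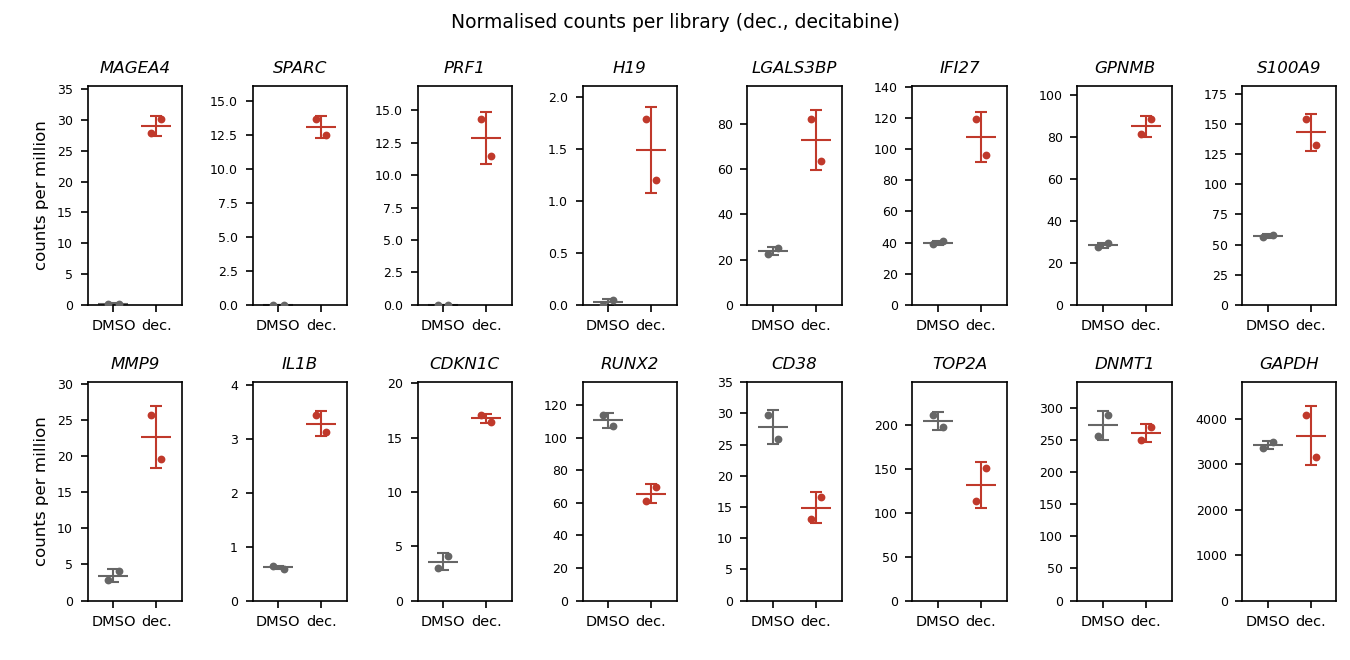
CPM of 16 named genes in each library (points), with the group mean and SD (n = 2), DMSO in grey and decitabine in red, on axes that start at 0. MAGEA4 reached 29 CPM from 0.155 CPM, and the libraries of the groups overlapped for DNMT1 and GAPDH.

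Cytosolic ribosomal protein genes were higher in 56 of 57 members, by a median of 0.28 on the log2 scale, with no single gene past the threshold over all genes or over the list alone (list adjusted p = 7.77e-09, and adjusted p = 0.645 with an estimated correlation, which was estimated at 0.848). The median was 0.12 without decitabine replicate 1 and 0.43 without decitabine replicate 2, where 33 members rose. Among other lists that were not called, 1 of 27 cholesterol and lipid genes rose (ABCG1, 0.373 to 2.40 CPM, adjusted p = 0.018, list adjusted p = 0.228). Of 23 genes of the unfolded protein and integrated stress response 1 rose (ATF5, 369 to 618 CPM, adjusted p = 0.0401, list adjusted p = 0.912), and of 20 replication-dependent histone genes 1 rose (H1-2, 1.13 to 3.07 CPM, adjusted p = 0.0496, list adjusted p = 0.312, and 0.0234 with the stricter filter, where the adjusted p = 0.417 with an estimated correlation). These 3 genes were also those that passed over their lists alone. The lipid list had 1 up and 6 down and the stress response list 3 up and 2 down without decitabine replicate 2. No gene passed over all genes in the lists for immune checkpoints and NK ligands (25 tested, list adjusted p = 0.171), glycolysis and hypoxia (27, 0.26), mitochondrially encoded genes (13, 0.274), oxidative stress and heat shock (23, 0.741), housekeeping (15, 0.89), the BCL2 family and apoptosis (26, 0.89) or G1/S and replication (43, 0.89). Genes did pass in these 7 lists without decitabine replicate 2, with 5 up for immune checkpoints, 2 down for glycolysis, 2 up and 1 down for mitochondrially encoded genes, 4 up and 4 down for oxidative stress, 1 down for housekeeping, 4 up and 4 down for the BCL2 family, and 1 up and 2 down for G1/S. In these 7 lists 1 gene rose when adjusted over the list alone, the quinone oxidoreductase gene NQO1 (55.9 to 90.5 CPM, adjusted p = 0.0743 over all genes). The mitochondrially encoded genes, a list chosen for RNA quality, were called lower without decitabine replicate 1 (adjusted p = 0.00375) and with offsets for GC content and length (adjusted p = 0.0263), and neither call held with an estimated correlation (adjusted p = 0.678 and 0.633). Their median log2 fold change of -0.11 was -0.209 without decitabine replicate 1, -0.225 without DMSO replicate 1, -0.0524 without DMSO replicate 2 and 0.04 without decitabine replicate 2. The G1/S list had a median of -0.02 (0.06 without DMSO replicate 1 and -0.07 without DMSO replicate 2), lower in camera and higher in fry.

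Fold changes followed the GC content of the transcripts. Over 18514 genes the Spearman correlation between GC content and log2 fold change was 0.52, across genes, which are not independent replicates. The median log2 fold change went from -0.35 in the lowest of 5 equal bins of expressed genes by GC content to 0.30 in the highest. Libraries of the same group also differed by GC content. The rho was 0.587 between DMSO 2 and DMSO 1 and -0.583 between decitabine 2 and decitabine 1. For decitabine 1 it was 0.751 against DMSO 1 and 0.609 against DMSO 2, and for decitabine 2 it was 0.621 and 0.317. Every pair of a decitabine and a DMSO library thus had a positive rho, so the trend also went with treatment. Log2 ratios also followed transcript length, with a rho of 0.525 between decitabine 2 and decitabine 1 but -0.0734 between DMSO 2 and DMSO 1. Against DMSO 1 and DMSO 2 it was -0.457 and -0.525 for decitabine 1, and -0.218 and -0.26 for decitabine 2. With offsets that remove each library's trend on GC content and length, chosen after seeing the data, 202 genes were called (183 up and 19 down), including 149 of the 236 that rose and 13 of the 29 that fell. The interferon list then had a median log2 fold change of 0.60 and the monocyte list 0.36 (adjusted p = 2.12e-32 and 8.7e-13), the G2/M list -0.20 (adjusted p = 1.29e-09) and the ribosomal protein list 0.21 (adjusted p = 1.12e-06). The neutrophil granule list went from 0.41 to 0.04 (adjusted p = 0.0071) and the DNA damage repair list from -0.21 to 0.005. With an estimated correlation none of these calls held (adjusted p = 0.15 for the interferon list, 0.155 for the monocyte list, 0.155 for G2/M, 0.633 for ribosomal proteins and 0.265 for neutrophil granules). Named genes that were not called with the offsets were AL445685.3, LSMEM1, USP32P2, AC078927.1, AP001931.2, GP1BA, ABCG1 and H1-2. The fitted log2 fold changes without and with offsets were -1.78 and -1.78 for AC078927.1, 2.67 and 2.59 for ABCG1, -3.43 and -3.25 for LSMEM1, -2.31 and -1.96 for USP32P2, and 1.43 and 1.03 for H1-2 (SE without offsets from 0.295 to 0.627). For AL445685.3 and GP1BA, without counts in a group, they were -11.03 and -11.02, and 8.04 and 7.98. AP001931.2 has no GC value, so the offsets corrected nothing in it. With the offsets the adjusted p of the 8 lay between 0.0506 and 0.126, and the lost calls do not show that GC content made these changes. These 8, except USP32P2, and BCL2L2-PABPN1, SLC28A3, ISG15, PSMB9, IGFBP3 and ATF5 were also not called with no filter on low counts. AC078927.1, BCL2L2-PABPN1, PSMB9 and ATF5 were not called without DMSO replicate 1, and H1-2 was not without decitabine replicate 1.

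**Figure D4:**
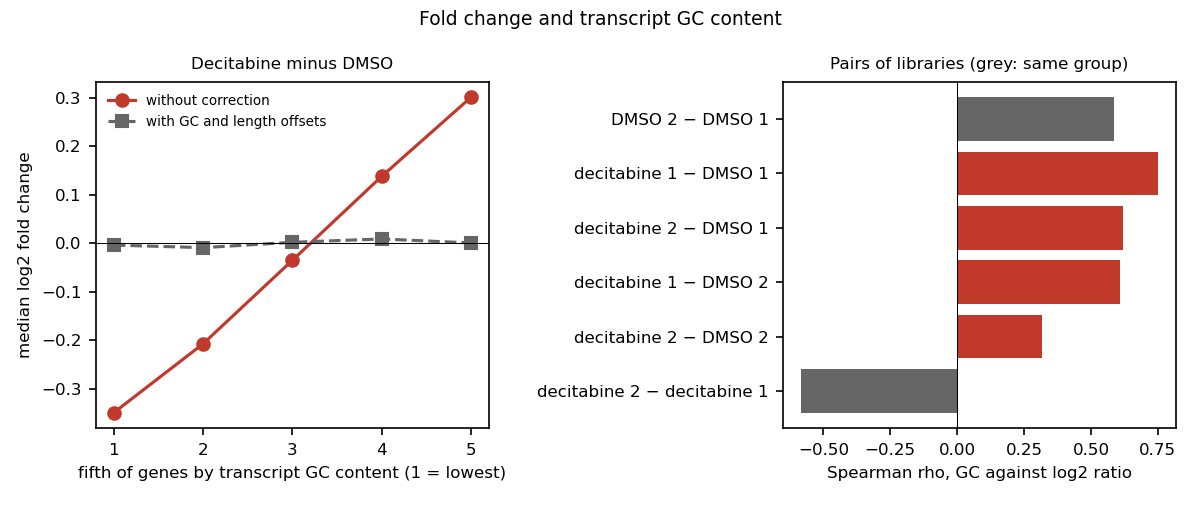
Left, median log2 fold change (decitabine minus DMSO) in 5 equal bins of genes by transcript GC content, without correction (red, from -0.35 to 0.30) and with GC and length offsets (grey). Right, Spearman rho across 12612 genes between GC content and the log2 ratio of 2 libraries, in grey for pairs of the same group, which lie at 0.587 and -0.583.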

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

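The GC and length offsets, limma on FPKM, the fit without overlapping gene models and the estimated correlation within another setting were chosen after seeing the data; the other alternatives were planned. Among the 265 genes called, no log2 fold change reversed under any alternative fitted to counts, and 1 did with limma on FPKM. RLE and upper quartile scaling gave 312 and 343 calls, with 265 of the 265 shared in each, and the 2-fold limit gave 234. Limma on FPKM gave 291, of which 133 were among the 265, with 110 of the 265 not tested. The counts moved more with no filter (125 calls, 117 up, 8 down), the stricter filter (450, 378 up, 72 down), the robust prior (420, 355 up, 65 down), DESeq2 (901, 622 up, 279 down), no overlapping gene models (414, 367 up, 47 down) and an unadjusted p with the 2-fold limit (860, 682 up, 178 down). Filters change both how many genes share the adjustment and which genes enter the variance fit. The cause was not tested for any of these settings. With GC and length offsets 19 genes fell instead of 29.

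With 1 library left out the calls ranged from 389 to 3934, the rises from 329 to 1748 and the falls from 60 to 2186; the lone library of a group is then assumed to vary like the other group. The highest of each came without decitabine replicate 2, where 263 of the 265 calls were shared. With the replicate number as a block 723 genes were called (560 up, 163 down), 265 of the 265 included, and 14 lists. The deviations of same-numbered libraries correlated at 0.01, while the second principal component (25% of the variance) split them by number, at 38.6 and 34.4 for number 1 and -42.5 and -30.5 for number 2. That is a hint only, and with 2 pairs the numbers were not taken to pair the libraries. The block changed no list call and lost no call of a named gene, and 16 named genes passed in addition.

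The 14 list calls became 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05, and 6 with fry. With an estimated correlation 0 were also called with GC and length offsets, without decitabine replicate 1, with the stricter filter and without overlapping gene models. The few residual degrees of freedom used there make calls hard whatever the correlation, so these losses alone do not separate the 2. The estimate was 0.848 for the ribosomal proteins and -0.00377 for the interferon list, so the part correlation could play differed between lists. Other settings gave 13 to 15 calls, including 12 to 14 of the 14; with no filter or a library left out the T and NK list, too small to test otherwise, was 1 of them. Of 47 called genes among the 116 named, 31 passed in every alternative that tested them. With no filter 15 lost the call, with GC and length offsets 8, without DMSO replicate 1 6, and without decitabine replicate 1, with the robust prior and with limma on FPKM 1 each. Pseudocounts were not run, since they do not apply to counts. Depth and 2 libraries per group limit small changes: the simulation recovered 43.6% of 2-fold changes.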

Other observations

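The tests of gene families, the X chromosome, exon overlap, other cell types and the share of rises with GC and length offsets, and the repeats without MAGEA4-AS1, were chosen only after the result was seen; those of single rises with offsets, of ribosomal proteins and of library pairs were written before theirs. Genes in this part were chosen after their values were seen, unless the rule for named genes took them. Grouping protein-coding genes by the letters of their symbol gave 238 families with at least 8 tested genes, and 6 of them held more risen genes than chance gives (one-sided Fisher's exact test with Benjamini-Hochberg adjustment, background 168 of 11283 genes). The IL family had 7 of 39 up (adjusted p = 0.000351), among them IL2RB, from 0.571 to 3.53 CPM, and the enzyme gene IL4I1, from 12.1 to 31.9 CPM. Keratins had 4 of 8 (adjusted p = 0.000377), with KRT81 from 0.215 to 6.94 CPM, although KRT81 and KRT86 are close paralogs with overlapping coordinates that can share reads. Collagens had 5 of 23 (adjusted p = 0.00148), ADAMTS proteases 4 of 14 (adjusted p = 0.00251), with ADAMTS15 from 0.527 to 5.13 CPM, CD antigens 7 of 66 (adjusted p = 0.00254) and matrix metalloproteinases 3 of 11 (adjusted p = 0.0194). With GC and length offsets the first 5 of these families passed again and the metalloproteinases did not (1 of 11, adjusted p = 1), while the IFI family passed in addition (4 of 9, adjusted p = 0.000136). CD52 rose from 0.964 to 28.7 CPM.

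Genes of the X chromosome were 14 of the 236 rises (5.93%, against 3.17% of the other genes tested, odds ratio 1.92 with a 95% interval of 1.03 to 3.32, Fisher's exact test, two-sided, p = 0.0244). The excess did not hold without MAGEA4-AS1, which overlaps MAGEA4 so that its reads cannot be separated without strand (13 of 235, Fisher's exact test p = 0.058), or with GC and length offsets (6 of 183, p = 0.834), where 5 of the 14 passed, so it stays open. Beside MAGEA4 the 14 include PNMA5, from 0.329 to 15.1 CPM, the germ cell gene GCNA, from 3.03 to 11.6 CPM, and CT45A1, a cancer-testis gene without a DMSO count that was at least 26.0-fold higher.

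The first pattern weighed is the falls in read-through and clone-named gene models. Of falling genes in the annotation 57.1% share exons on the same strand. The 15 partners examined, 1 per model, had a median log2 fold change of 0.13, between -0.52 and 0.90. A candidate explanation is therefore that reads were assigned to another overlapping model. That does not account for the falling genes without overlap on either strand, of which 3 of 6, RUNX2, CD38 and AL390728.6, also passed with GC and length offsets. A change in transcript choice with decitabine was not tested and stays open for the overlapping models.

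The second pattern is the rise of lymphocyte, collagen and keratin genes. T or NK cells mixed into the decitabine cultures would bring their other abundant transcripts, but the other 21 markers of that list had a median rise of 0 CPM, and GNLY, GZMB and CD3E had no count in any library, although NKG7 went from 16.8 to 26.2 CPM and IL7R from 3.91 to 4.97 CPM. For fibroblasts or epithelial cells the other 18 markers had a median rise of 0.0083 CPM, with KRT18 and COL1A2 at 0.0186 CPM against 10.2 CPM for KRT8 and 6.53 CPM for COL1A1. The rise replaced a first test on their median level with decitabine, which at 0.121 CPM (0.0323 CPM in DMSO) had decided nothing. Of these 18 markers 3 were higher by over 1 CPM, CLDN7 from 39.5 to 51.2 CPM, COL6A1 from 41.7 to 73.3 CPM and PDGFRB from 1.01 to 2.82 CPM, as such cells would also bring, and no biological explanation was tested.

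The third pattern is the link between fold change and GC content, together with the excess of rises. A GC bias that differs from library to library is a candidate source of the trend. Libraries of the same group differed with a rho as large as 0.587. All pairs of a decitabine and a DMSO library had a positive rho, from 0.317 to 0.751, so a trend that goes with treatment stays open. A length trend was also present, weak between the DMSO libraries (rho -0.0734) and marked between the decitabine libraries (0.525). Length was not tested apart from GC content. The trends that the offsets remove do not account for the whole excess of rises in these 4 libraries, which was 90.6% of calls with the offsets. The exact binomial 95% interval (85.7% to 94.2%) treats genes as independent, which they are not, so it does not measure the full uncertainty. The excess itself was 69% with DESeq2 and turned without decitabine replicate 2. For single genes the answer is mixed: 63.1% of rises passed with the offsets. The 87 that did not had a median log2 fold change of 2.08 without offsets (median SE 0.379) and 1.86 with them. Whether GC or length bias contributed to those calls cannot be told apart. For the ribosomal protein list the offsets left a median of 0.21 of 0.28, which leaves GC or length bias open. The median of 0.116 without decitabine replicate 1 shows that much of it may come from that library.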
